A study of Homo sapiens with 5 samples.

How the data were processed

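RNA of cultured human osteosarcoma cells was measured in 5 libraries, 1 for each of HOS control, OS-R Cisshock, OS-R without Cisplatin, HOS Cisshock and HOS Revived. Per the labels, RNA was extracted with TRIzol and sequenced on an Illumina instrument. Per the submitters' processing notes, reads were converted with bcl2fastq, aligned to hg38 with TopHat2 2.0.11 and assembled and quantified with Cufflinks 2.2.1 and Cuffdiff. The deposited values are FPKM, given with 2 decimals for 15288 gene entries in each library, and no read counts or reads were available. Whole reads could not be recovered, since the values under 0.5 took 49 distinct levels at steps of 0.01, so the depth of each library and the counting error of each value are unknown. Entries at 0 numbered 697 in HOS control, 350 in OS-R Cisshock, 640 in OS-R without Cisplatin, 1153 in HOS Cisshock and 479 in HOS Revived, and entries of at least 1 FPKM numbered 12860, 13169, 12792, 11724 and 13119.

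Symbols and identifiers were matched to RefSeq genes on GRCh38.p14, which placed 15231 entries and left 57 unplaced, with 0 repeated symbols. They comprised 12292 protein-coding genes, 1523 long noncoding RNAs and 795 microRNAs, and 1011 entries carried small RNA symbols, whose FPKM is unreliable at their length. Transcript GC content and the nearest coding gene at lower coordinate on the same strand were taken from the reference, with GENCODE release 29 for transcript sequences, and 14817 entries had both strand and GC content. Entries were read under the symbols the authors gave and were not renamed.

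Samples were grouped by their titles. The differences of log2(FPKM + 1) were computed for 6 comparisons, namely each of the other 4 groups minus HOS control, OS-R Cisshock minus OS-R without Cisplatin, and HOS Cisshock minus HOS Revived. All 4 comparisons with HOS control share that library. With 1 library per group no test between groups was possible. An entry was called higher or lower at a difference of at least 2-fold with at least 1 FPKM in either library. Pairs of libraries were compared by Spearman correlation and by the number of called entries. The 10 ways to part the 5 libraries 2 against 3 were counted by entries 2-fold apart between all libraries of the parts, and single libraries were compared with the other 4 likewise.

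Gene lists numbering 31 were fixed before the data were examined, as were the comparisons, call rule, naming rule and the first set of alternatives. The lists held p53 targets, S-phase genes, G2/M and mitosis genes, replication-dependent histones, nucleotide excision and crosslink repair genes, platinum transporters, NRF2 targets, metallothioneins, amino acid stress genes, unfolded protein response genes, heat shock genes, interferon-stimulated genes, NF-kB genes, immediate early genes, YAP and TAZ targets, mesenchymal genes, collagens and bone matrix, osteoblast genes, stem cell genes, BCL2 family genes, autophagy and lysosome genes, cholesterol synthesis genes, hypoxia and glycolysis genes, oxidative phosphorylation genes, ribosomal protein genes and housekeeping genes. Epithelial, blood, endothelial and neural markers stood for other cell types. The mitochondrially encoded genes had fewer than 3 entries and were left out, which left 30 lists. The median difference of the measured members was placed among the medians of 10000 random lists of the same size drawn from the same 20 bins of expression level. A list stood apart when its percentile was under 2.5 or over 97.5, which 5% of lists of genes that vary independently would do by chance.

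Named genes were the 12 largest differences each way for the comparisons with HOS control and the 10 largest each way elsewhere, among entries of at least 5 FPKM in the higher library, leaving out small RNAs, XIST and Y-linked genes, plus up to 4 members of each list with the largest difference and members that answer what the list is about. Some genes picked by this rule are not reported here. Alternatives fixed in advance were pseudocounts of 0.1 and 5 in place of 1, no filter, a filter of 5 FPKM, median-ratio scaling, rescaling to a sum of 1000000, quantile scaling, and leaving out small RNAs. Further alternatives, added after the data were seen, were centring within 20 bins of transcript GC content, centring on the GC content of the entry and of its lower neighbour, leaving out HOS Cisshock, and reading each listed gene from its own or the next same-strand entry, whichever had the higher mean, and exchanging the labels of OS-R without Cisplatin and HOS Revived for the correlation of the drug differences of the 2 lines.

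The computation was tested on simulated data of the same size with 200 altered genes and noise of 0.2 on the log2 scale. At a log2 difference of 1.5 it recovered 97.2, 93.1, 100, 98.5, 98.4 and 98.3% of the altered genes in the 6 comparisons in the order above, and all of them at 2 and 3, while it called 0% of the unaltered genes. That noise lay far inside the 2-fold rule, so the 0% could hardly have come out otherwise. Between real libraries the log2 differences had a standard deviation of 0.559 to 1.58, real differences included. The rate of false calls in these libraries therefore remains unknown. Of 200 null lists of size 30, between 5.0 and 6.5% fell outside the limits. Their values were drawn independently for each gene, so this says nothing on lists of genes that vary together. GC centring removed 96.7% of an added GC trend. That trend followed the GC content of each entry itself, without displaced values. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.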

Results

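RNA of 5 samples of human osteosarcoma cells was sequenced, each sample standing for a stage on the way to chemoresistance. HOS is an established osteosarcoma cell line, and OS-R is a derivative of it that resists cisplatin, a platinum drug that crosslinks DNA. HOS control was the untreated parental line, HOS Cisshock the parental line after a cisplatin shock whose dose the labels do not give, and HOS Revived the parental line described as revived and without cisplatin. OS-R Cisshock was the resistant line given 1 mg per ml cisplatin, and OS-R without Cisplatin the resistant line grown for 14 days without the drug. The title and treatment of the OS-R Cisshock sample name a shock, while the name attached to its deposited values says only OS-R, which the growth protocol uses for resistant cells kept in cisplatin. The title was followed, and whether these values come from shocked or from maintained cells remains open.

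The authors deposited FPKM for the same 15288 gene entries in each library, summing to 439722 in HOS control, 368380 in OS-R Cisshock, 451238 in OS-R without Cisplatin, 892407 in HOS Cisshock and 390179 in HOS Revived. The 10 most abundant entries held 8.64, 12.4, 8.65, 10.7 and 10.4% of these sums in the same order. Each group had 1 library, so no difference below has a replicate check and none has a p-value. Sequencing depth could not be read from FPKM, and a value of 0 need not mean a silent gene, since genes of housekeeping type such as RPL37A were listed at 0 as well. Differences are on the scale of log2(FPKM + 1), which understates them for weakly expressed genes. An entry counted as higher or lower when it was at least 2-fold apart on that scale and had at least 1 FPKM in either library.

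Several of the most abundant transcripts of human cells were not found under their own symbols. EEF1A1, which encodes a translation elongation factor, was listed at 4.28 FPKM in HOS control, while SLC17A5, a lysosomal transporter gene and the next entry on the same strand, was listed at 4295. RPL26, a ribosomal protein gene, stood at 0.28 beside RNF222 at 2634, and RPL37A at 0 beside IGFBP2 at 2858. ACTB and RPS27, encoding cytoplasmic actin and a ribosomal protein, had no entry, while RNF216 and UBAP2L next to them stood at 3113 and 4284. RPLP1 at 5216, GAPDH at 2790, RPLP0 at 2046 and VIM at 902 were abundant under their own symbols. Of 77 cytosolic ribosomal protein genes, 59 had an entry of their own, with a median log2(FPKM + 1) of 6.96 over those entries. Over all 77 genes, those without an entry included, the median was 9.96 for the next entries on the same strand and 2.80 for the previous ones. The next entry was the higher in 32 of the 59 genes with an own entry and the own entry in 27. Olfactory receptor genes, normally silent outside the nose, had 28 entries, of which 11 reached 5 FPKM in HOS control and the highest reached 100.

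Values below are those of a gene's own entry, and the same-strand coding gene at the next lower coordinate is called its lower neighbour and named beside the entries with the largest differences of each comparison. Each list result was also read from whichever of the own and the next entry had more FPKM on average, a readout added after the displaced entries were seen. Where that readout ended or turned a list result, its value is given, and a list said not to stand apart was judged by own entries.

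**Figure D1:**
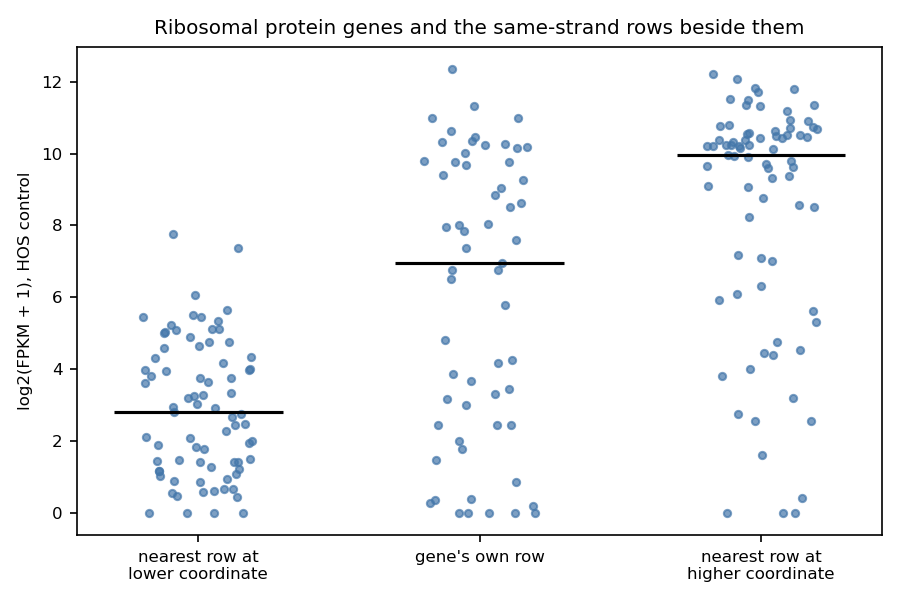
Log2(FPKM + 1) in HOS control for ribosomal protein genes, read from the nearest same-strand entry at lower coordinate, the gene's own entry and the nearest same-strand entry at higher coordinate. Each dot is a gene and each line a median.

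HOS control and OS-R without Cisplatin were the most alike of the 10 library pairs, with a Spearman correlation of 0.949 and 871 entries at least 2-fold apart. HOS Revived stood at 0.918 with HOS control, 0.917 with OS-R without Cisplatin and 0.905 with OS-R Cisshock, with 1748, 1803 and 1794 entries. The 2 OS-R libraries were less alike, at 0.867 with 3570 entries. HOS Cisshock lay far from each of the other libraries, with correlations of 0.697 to 0.798 and between 7325 and 8559 entries at least 2-fold apart. Among entries set apart in a single library, 2795 were higher and 1969 lower in HOS Cisshock, 295 and 352 in OS-R Cisshock, 66 and 63 in HOS Revived, 57 and 45 in OS-R without Cisplatin, and 53 and 61 in HOS control. For HOS Cisshock fewer were higher than lower after median-ratio scaling, with 1792 and 2355, quantile scaling, with 956 and 1749, rescaling to an equal sum, with 168 and 4446, and GC centring, with 1134 and 1577. For OS-R Cisshock more were higher than lower under the same settings in the same order, with 421 and 260, 420 and 305, 706 and 286, and 394 and 277.

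**Figure D2:**
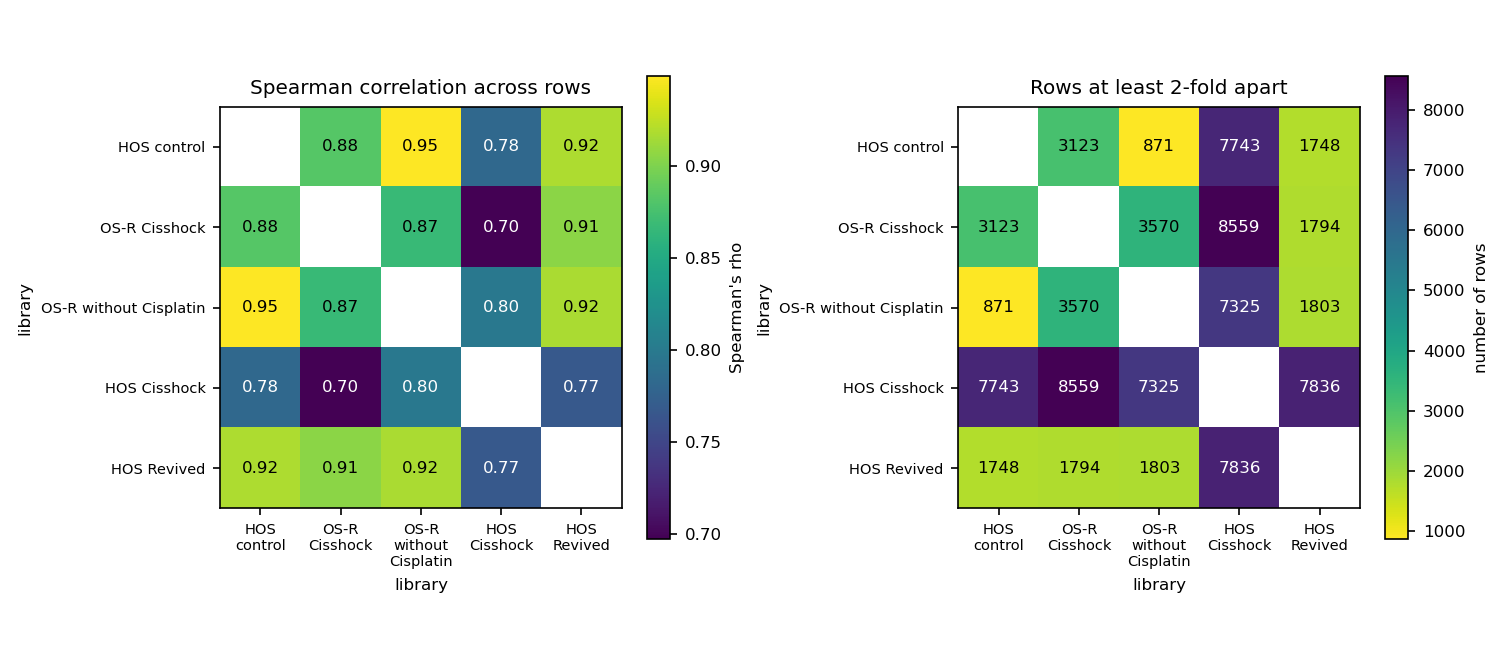
Spearman correlation across entries and the number of entries at least 2-fold apart for each of the 10 pairs of libraries. Pale and dark cells follow the colour bars beside the panels.

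What cisplatin shock was accompanied by in the parental line is answered by HOS Cisshock against HOS control. Genes of G2/M and mitosis were lower at the median in HOS Cisshock as deposited, with CDK1, the kinase that drives entry into mitosis, at 5.84 FPKM against 68.6 and ECT2, a RhoA activator needed for cytokinesis, at 0.93 against 14.0. Collagen and bone matrix genes were lower too, with COL12A1, a fibril-associated collagen, at 5.35 against 24.5 and PLOD2, a collagen lysyl hydroxylase, at 4.55 against 36.3. Heat shock genes were lower at the median, led by HSP90AA1, a cytosolic chaperone, at 88.7 against 569. Replication-dependent histone genes and epithelial markers were higher at the median as deposited, including H2AC6 at 28.5 against 9.59 and the keratin gene KRT18 at 35.2 against 8.88.

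Among 47 measured G2/M and mitosis genes, 21 were lower, 13 higher and 13 under 2-fold, with a median log2 difference of -0.49 at percentile 0.15 of random lists of equal size and level. DLGAP5 and HMMR, both spindle factors, were listed at 1.52 against 15.4 and 0.52 against 8.04. The 20 collagen and bone matrix genes split into 9 lower, 4 higher and 7 under 2-fold, with a median of -0.46 at percentile 1.33, and FBN2, a fibrillin, stood at 2.05 against 12.6. Of 12 heat shock genes, 6 were lower and 4 higher with a median of -0.21 at percentile 1.47. HSPH1, a large chaperone, was at 7.97 against 52.2, while the co-chaperone genes STIP1 at 5.13 against 0.41 and DNAJB1 at 20.3 against 4.08 were higher. FERMT3, for which STIP1 is the lower neighbour, was far more abundant and at 379 against 147. Of 19 histone genes, 9 were higher and 1 lower with a median of 0.76 at percentile 99.7, led by H2AC14 at 5.18 against 0.45. Of 8 epithelial markers, 7 were higher and none lower with a median of 1.65 at percentile 99.5, and EPCAM, an adhesion protein gene with TTC7A as lower neighbour, stood at 3016 against 592. PRSS8 and ESRP2, a membrane protease and a splicing regulator of epithelia, were at 50.9 against 13.0 and 25.8 against 7.13. Reading from the own or next entry turned the heat shock median to 0.60 at percentile 9.21, limiting it to entries of at least 5 FPKM turned it to 0.68, and the first of these moved the collagen median to -0.07 at percentile 2.53.

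Abundant glycolytic genes were among the higher entries, with ENO1 at 3107 against 834, TPI1 at 2159 against 588 and PKM at 2449 against 675, all enzymes of glycolysis. Their list as a whole, with a median of 0.65 over 26 genes, lay at percentile 45.6 of lists of equal level, as did ribosomal protein genes with a median of 1.02 over 53 genes at percentile 39.1, though at percentile 0.26 with the own or next entry. Nuclear-encoded oxidative phosphorylation genes had a median of 1.11 over 42 genes at percentile 80.2, and at 99.2 after GC centring, with NDUFA11, a complex I subunit gene, at 725 against 173. ITGB1 and ITGAV, which encode integrin subunits, were lower at 15.2 against 139 and 5.86 against 48.6. BIRC2, encoding an inhibitor of apoptosis, was at 2.35 against 37.9.

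Among the largest single differences, GMEB1 (chromosome 1, 28668229 to 28719353, GRCh38), with RAB42 as lower neighbour, stood at 149 against 2.95, and BASP1, encoding a membrane-bound signalling protein and beside FBXL7, at 27.0 against 0.62. TAF4 (chromosome 20, 61974798 to 62065881), with PPP1R3D as lower neighbour, was at 5.14 against 285, TBR1 beside PSMD14 at 0.01 against 40.5, and CD164 beside SESN1 at 0.37 against 26.0. SERINC4 beside ELL3 and PLOD1 beside CLCN6 were at 8067 and 640 in HOS Cisshock and listed at 0 in HOS control. LRP4 beside CKAP5 was at 547 in HOS control and listed at 0 in the other 4 libraries. TAF4 was also high in HOS control only, at 3.87 to 5.14 elsewhere. Of the 24 largest differences, 14 had a 0 on either side.

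In total 4266 entries were higher and 3477 lower in HOS Cisshock, with 6181 under 2-fold. The higher share of 55.1% was 46.3% after median-ratio scaling, 12.2% after rescaling each library to an equal sum and 47.0% after quantile scaling, and the median of all entries moved from 0.27 to 0.05 and -0.65 with the first 2. Differences were larger in transcripts of higher GC content, with a Spearman correlation of 0.584, from a median of -1.36 in the lowest of 20 GC bins to 1.26 in the highest. Entries on chromosome 19, rich in GC, had a median of 1.21, and those on chromosomes 13 and 4 had medians of -0.77 and -0.67. Centring each GC bin left the collagen result at -0.79 and percentile 0.02. It moved the G2/M and mitosis genes to 0.04 at percentile 13.7, histone genes to percentile 96.1, heat shock genes to percentile 2.86 and epithelial markers to percentile 85.4, so those 4 lists no longer stood apart. Rescaling to an equal sum turned the histone median to -0.14.

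**Figure D3:**
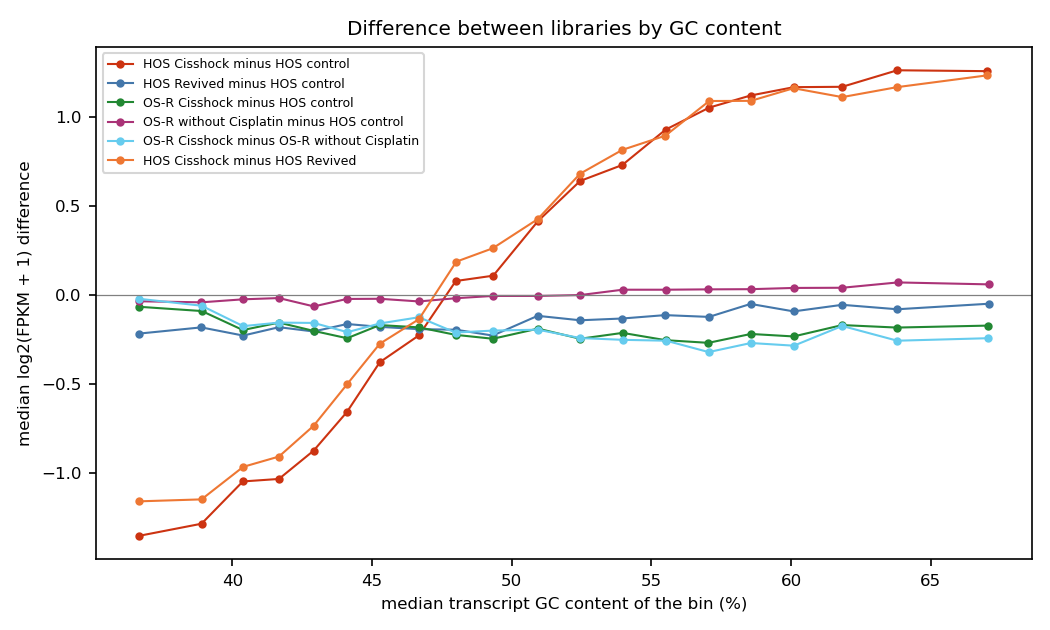
Median log2(FPKM + 1) difference of each of 20 GC bins against the median GC content of their transcripts in percent. Each line is a comparison, and the grey line marks no difference.

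How parental cells revived without the drug differed from untreated cells is answered by HOS Revived against HOS control. Genes of S phase, G2/M and mitosis were lower in HOS Revived, with RRM2, a ribonucleotide reductase subunit, at 2.2 FPKM against 10.3 and MKI67, a proliferation marker, at 4.4 against 18.0. Heat shock, amino acid stress and glycolysis genes were lower at the median as well, though most of their members were under 2-fold apart. Interferon-stimulated genes and collagens were higher, with IFI6, an interferon-induced mitochondrial protein gene, at 21.9 against 10.6 and COL1A2, a type I collagen chain with GNG11 as lower neighbour, at 122 against 27.2. MMP2, a matrix-degrading protease gene with IRX6 as lower neighbour, stood at 40.6 against 3.78, and ACTA2, smooth muscle actin, at 244 against 58.7.

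Of 47 G2/M and mitosis genes, 21 were lower and none higher with a median of -0.94 at percentile 0, and 43 lay below HOS control by any amount. ANLN, a cytokinesis scaffold gene beside EEPD1, was at 2.71 against 27.3 and CDCA8, of the chromosomal passenger complex, at 7.09 against 28.3. Of 40 S-phase genes, 8 were lower and 1 higher with a median of -0.63 at percentile 0, including HELLS, a chromatin remodeller, at 2.57 against 10.2 and UHRF1, which maintains DNA methylation, at 15.4 against 36.5. Of 11 heat shock genes, 4 were lower and 7 under 2-fold with a median of -0.89 at percentile 0.02, with HSPD1, a mitochondrial chaperonin, at 195 against 461 and HSP90AA1 at 241 against 569. Amino acid stress genes driven by ATF4 had a median of -0.50 over 18 genes at percentile 1.4, with 3 lower and 15 under 2-fold. PSAT1 and MTHFD2, enzymes of serine and one-carbon metabolism, were at 3.40 against 14.6 and 49.7 against 124. Targets of YAP and TAZ, growth regulators of the Hippo pathway, had a median of -0.59 over 14 genes at percentile 0.85, with 2 lower by 2-fold, AXL at 32.2 against 87.3 and ASAP1 at 7.25 against 17.6.

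Of 20 interferon-stimulated genes, 3 were higher by 2-fold and 19 by any amount with a median of 0.55 at percentile 100. The 3 were OAS3, OASL and IFIH1, each under 5 FPKM in both libraries. Members higher by under 2-fold included IFITM3 beside IFITM5 at 230 against 155 and IFITM1 at 78.9 against 56.8, both encoding membrane proteins that block viral entry. Of 20 collagen and bone matrix genes, 4 were higher, 2 lower and 14 under 2-fold with a median of 0.48 at percentile 100. COL11A1 was at 17.3 against 5.29 and DCN, a proteoglycan gene beside LUM, at 8.86 against 2.03, while COL8A1 was lower at 5.22 against 23.6. Ribosomal protein genes stood above lists of equal level with a median of 0.03 over 54 genes at percentile 99.9, with 3 higher and 51 under 2-fold, the 3 being RPL12, RPL22 and RPL37A, each under 2 FPKM in both libraries. Glycolysis and hypoxia genes had a median of -0.57 over 23 genes at percentile 0.20, with 2 lower by 2-fold, HK2, the hexokinase gene, at 3.38 against 12.1 and VEGFA, an angiogenic factor gene, at 2.31 against 5.68. Reading from the own or next entry moved that list to -0.34 at percentile 12.2.

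Targets of p53, the DNA damage regulator, had a median of 0.21 over 23 genes at percentile 99.2, with 3 higher and 1 lower, and BBC3, a pro-apoptotic BCL2 family gene, at 6.31 against 1.79. NRF2 targets of the antioxidant response had a median of 0.04 over 27 genes at percentile 98.8, with NFE2L2, the gene of NRF2 itself, at 10.5 against 4.57 and MGST1, a glutathione transferase, at 50.3 against 111. Neural markers had a median of 0.41 over 7 genes at percentile 97.9, none 2-fold apart, and their most abundant member GFAP, beside EFTUD2, was lower at 60.4 against 94.0. With the own or next entry these 3 medians turned to -0.16, -0.03 and -0.23, and p53 targets and neural markers no longer stood apart, while NRF2 targets still did at percentile 98.8. Among entries of at least 5 FPKM the neural median was -0.45.

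SMURF2 (chromosome 17, 64542282 to 64662307), encoding a ubiquitin ligase and with the helicase gene DDX5 as lower neighbour, was listed at 1731 against 6.23, and GABBR1 (chromosome 6, 29602238 to 29633183), beside UBD, at 42.5 against 3.23. MUC20, a mucin gene beside FAM43A, and SELENOW beside NOP53 stood at 797 and 248 and were listed at 0 in HOS control. KIAA2013 beside NPPB (chromosome 1, 11919591 to 11926427) was lower at 57.7 against 677, as was ZP3 beside HSPB1 at 4.41 against 52.0 and TAF12 beside DNAJC8 at 0.46 against 64.5. TAF12 was high in HOS control only, at 0.44 to 8.2 elsewhere, and SMURF2 in HOS Revived only, at 0.71 to 6.23 elsewhere. Of the 24 largest differences, 13 had a 0 on either side. In total 740 entries were higher, 1008 lower and 12267 under 2-fold. The higher share of 42.3% was 55.4% after median-ratio scaling, 59.3% after rescaling to an equal sum and 51.5% after quantile scaling, with the median of all entries moving from -0.15 to -0.02 with median-ratio scaling.

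How the resistant line in cisplatin differed from the parental line is answered by OS-R Cisshock against HOS control. Cell cycle, glycolysis, oxidative phosphorylation, heat shock and metallothionein genes were lower in OS-R Cisshock, with LDHA, the lactate dehydrogenase gene, at 84.9 FPKM against 754 and MT1L, a metallothionein entry beside MT2A, at 219 against 1430. Amino acid stress, unfolded protein response and interferon-stimulated genes were higher, with SLC3A2, an amino acid transporter subunit, at 175 against 57.2 and IFITM3 beside IFITM5 at 463 against 155. Several matrix genes were higher too, with MMP2 at 42.2 against 3.78 and COL11A1 at 27.4 against 5.29. The control library is shared with the HOS Revived comparison, so the lists that stood apart in both are not separate observations.

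Of 48 G2/M and mitosis genes, 26 were lower and 1 higher with a median of -1.06 at percentile 0, including ANLN beside EEPD1 at 2.28 against 27.3, KIF23, a cytokinesis motor gene, at 8.07 against 36.5 and TPX2, a spindle assembly factor, at 0.40 against 7.09. Of 38 S-phase genes, 12 were lower and none higher with a median of -0.79 at percentile 0, with CDC45, a replicative helicase subunit, at 8.94 against 33.6 and RRM2 at 1.63 against 10.3. Of 11 heat shock genes, 7 were lower with a median of -1.26 at percentile 0.07, HSP90AA1 being at 147 against 569 and DNAJA1 at 24.7 against 64.0. Of 23 glycolysis and hypoxia genes, 10 were lower and 1 higher with a median of -0.85 at percentile 0.33, GPI being at 29.3 against 110 and TPI1 at 169 against 588. Of 44 oxidative phosphorylation genes, 12 were lower and 4 higher with a median of -0.72 at percentile 0.38, and ATP5MC1, a subunit of ATP synthase, stood at 94.3 against 398. Of 5 metallothioneins, small proteins that bind metals, 3 were lower and 1 higher with a median of -2.08 at percentile 0, with MT1M beside MT1E at 57.7 against 328 and MT1G at 14.9 against 6.77. The own or next entry moved the metallothioneins to -0.97 at percentile 6.36. Housekeeping genes had a median of -0.87 over 12 genes at percentile 1.07, with GAPDH at 1121 against 2790 and YWHAZ at 77.5 against 197, and lay at percentile 9.06 with the own or next entry.

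Of 19 amino acid stress genes, 7 were higher and 1 lower with a median of 0.61 at percentile 100, including ALDH1L2, a mitochondrial folate enzyme, at 11.3 against 2.11 and PCK2, of gluconeogenesis, at 38.4 against 12.5, while PSAT1 was lower at 4.31 against 14.6. Of 16 unfolded protein response genes, 2 were higher, 1 lower and 13 under 2-fold with a median of 0.48 at percentile 100. The 2 higher were SEL1L, of the degradation pathway of the endoplasmic reticulum, at 55.1 against 20.6 and CRELD1, a gene of the endoplasmic reticulum, at 6.27 against 0.85. HSPA5, the main chaperone of the endoplasmic reticulum, was lower at 3.22 against 13.6 under its own symbol beside PPP6C, but MAPKAP1, for which HSPA5 is the lower neighbour, was higher at 583 against 243. Of 24 interferon-stimulated genes, 9 were higher and none lower with a median of 0.88 at percentile 100, with IFI6 at 37.4 against 10.6 and IFIH1, an RNA sensor gene, at 5.46 against 1.03. Among the higher members, only IFI6, IFIH1 and IFITM3 reached 5 FPKM in either library. Of 20 collagen and bone matrix genes, 7 were higher and 1 lower with a median of 0.23 at percentile 99.9, including DCN beside LUM at 19.8 against 2.03 and COL6A3 at 9.25 against 0.52. Ribosomal protein genes had a median of 0.17 over 53 genes at percentile 100, with 7 higher and 3 lower, RPL37 being at 229 against 27.2 and RPL8 at 36.5 against 107. The next same-strand entries, both under small RNA symbols, were more abundant. SNORD72 after RPL37 was at 839 against 538, and MIR6850 after RPL8 was at 2024 against 1768, so the fall of RPL8 was not seen there.

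GLI1 (chromosome 12, 57459785 to 57472268), with INHBE as lower neighbour, was listed at 26.9 against 0.98, and GPR108 (chromosome 19, 6729914 to 6737580), beside the complement gene C3, at 51.5 against 2.15. DHX15 beside PPARGC1A stood at 568 in OS-R Cisshock and was listed at 0 in the other 4 libraries. XRCC5 (chromosome 2, 216109348 to 216206293), a gene of DNA end joining beside TMEM169, was lower at 0.19 against 31.7, and BBS2 beside NUDT21 was lower at 0.54 against 35.8. Of the 24 largest differences, 12 had a 0 on either side. In total 1167 entries were higher, 1956 lower and 11034 under 2-fold. The higher share of 37.4% was 54.5% after median-ratio scaling, 57.8% after rescaling to an equal sum and 51.6% after quantile scaling, and the median of all entries moved from -0.19 to 0.01 with median-ratio scaling.

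**Figure D4:**
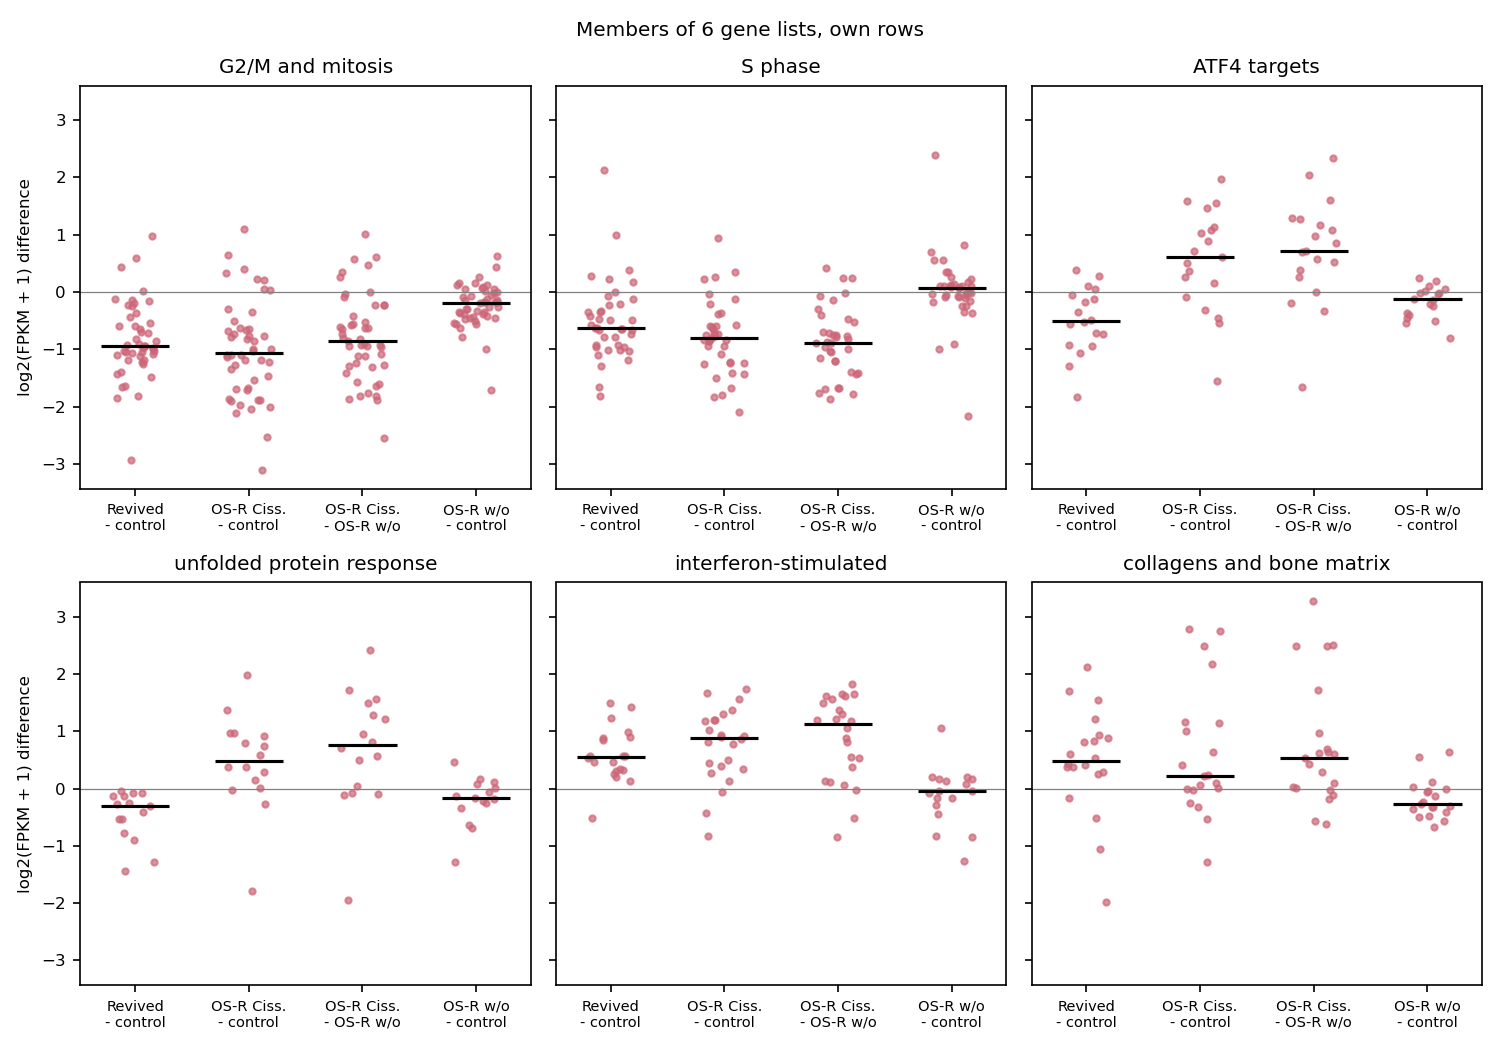
Log2(FPKM + 1) differences of the members of 6 gene lists, own entries, in 4 comparisons. Each dot is a measured gene and each line a median.

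How the resistant line held without the drug differed from the parental line is answered by OS-R without Cisplatin against HOS control. Collagens, cholesterol synthesis genes and G2/M genes were slightly lower in OS-R without Cisplatin, and few of their members were 2-fold apart. IDI1, an isomerase of cholesterol synthesis, was at 6.72 FPKM against 13.9, and COL8A1 at 14.5 against 23.6. TPX2, needed for spindle assembly, was at 1.48 against 7.09 under its own symbol and was the single G2/M member lower by 2-fold. MYLK2, for which TPX2 is the lower neighbour, was far more abundant and under 2-fold apart, at 67.4 against 82.5.

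Of 48 G2/M and mitosis genes, 36 lay below HOS control by any amount with a median of -0.19 at percentile 0, NEK2, a centrosomal kinase gene, being at 7.19 against 13.1. Of 19 collagen and bone matrix genes, 15 lay below, none by 2-fold, with a median of -0.28 at percentile 0, COL1A2 beside GNG11 being at 18.0 against 27.2. Of 20 cholesterol synthesis genes, 15 lay below and 1 was lower by 2-fold with a median of -0.21 at percentile 0.01. Hypoxia and glycolysis genes had a median of -0.11 over 22 genes at percentile 0.42, none 2-fold apart, with VEGFA at 3.17 against 5.68. Unfolded protein response genes had a median of -0.16 over 15 genes at percentile 1.54, SEL1L being at 16.1 against 20.6, and lay at percentile 6.09 with the own or next entry.

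SHE (chromosome 1, 154469637 to 154502412), encoding an adaptor protein and beside LTAP1, was higher in OS-R without Cisplatin at a log2 difference of 4.33, TAFAZZIN beside RPL10 was at 49.8 against 2.06 and SERPINH1, a collagen chaperone gene beside RPS3, at 22.9 against 0.46. STON2 beside GTF2A1 was at 42.0 against 2.09 and FAM72C beside H3-7 at 18.4 against 1.55. PNPLA2 beside RPLP2 and RIDA beside RPL30 stood at 73.6 and 68.0 and were listed at 0 in HOS control, as was SERINC4, which stood at 2567. VCP (chromosome 9, 35056064 to 35072625), an ATPase gene beside SPATA31F3, was lower at 2.81 against 25.4, and P4HB beside PPP1R27 was at 17.1 in HOS control and listed at 0 here. FANCG, for which VCP is the lower neighbour, was far more abundant than the VCP entry in OS-R without Cisplatin. Of the 24 largest differences, 12 had a 0 on either side. In total 447 entries were higher, 424 lower and 12808 under 2-fold, a higher share of 51.3%.

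What the drug was accompanied by within the resistant line is answered by OS-R Cisshock against OS-R without Cisplatin. Amino acid stress, unfolded protein response, interferon-stimulated and collagen genes were higher in OS-R Cisshock, with PCK2 at 38.4 FPKM against 8.56, SEL1L at 55.1 against 16.1, IFI6 at 37.4 against 12.02 and COL1A2 beside GNG11 at 61.4 against 18.0. Cell cycle, heat shock, antioxidant and metallothionein genes were lower, with UHRF1 at 13.0 against 43.9, HSPA8, a constitutive cytosolic chaperone, at 585 against 1578 and PRDX1, a peroxide-removing enzyme, at 145 against 548. VEGFA was higher at 17.2 against 3.17, while LDHA was lower at 84.9 against 702.

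Of 24 interferon-stimulated genes, 13 were higher and none lower with a median of 1.12 at percentile 100, including IFIH1 at 5.46 against 0.82 and IFITM3 at 463 against 151. Among the higher members, only IFIH1, IFITM3 and IFI6 reached 5 FPKM in either library. Of 16 unfolded protein response genes, 6 were higher and 1 lower with a median of 0.75 at percentile 100, CRELD1 being at 6.27 against 0.36 and HERPUD1 at 5.87 against 1.33. Of 19 amino acid stress genes, 7 were higher and 1 lower with a median of 0.71 at percentile 100, ALDH1L2 being at 11.3 against 1.41. Of 21 collagen and bone matrix genes, 5 were higher and none lower with a median of 0.54 at percentile 100, DCN beside LUM being at 19.8 against 1.14 and COL6A3 at 9.25 against 0.81. Mesenchymal genes had a median of 0.09 over 29 genes at percentile 97.8, with 7 higher and 2 lower, MMP2 at 42.2 against 5.00, S100A4 at 7.74 against 1.84 and TAGLN, an actin-binding protein gene, at 9.46 against 57.2. Their median turned to -0.12 with the own or next entry, to -0.07 among entries of at least 5 FPKM, and lay at percentile 95.6 after GC centring.

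Of 36 S-phase genes, 14 were lower and none higher with a median of -0.88 at percentile 0, CDC45 being at 8.94 against 35.2 and UNG, a uracil glycosylase gene, at 14.2 against 51.1. Of 47 G2/M and mitosis genes, 17 were lower and 1 higher with a median of -0.86 at percentile 0, BIRC5, a passenger complex gene that encodes survivin, being at 1.76 against 9.11. Of 12 heat shock genes, 6 were lower with a median log2 difference of -1.11 at percentile 0.32. Of 27 NRF2 targets, 9 were lower and 1 higher with a median of -0.82 at percentile 0.66, including SRXN1, a sulfiredoxin gene, at 3 against 17 and ME1, the malic enzyme gene, at 2.02 against 9.6. Of 33 genes of nucleotide excision and crosslink repair, 6 were lower and 1 higher with a median of -0.60 at percentile 1.75, with the Fanconi anaemia gene FANCI at 11.5 against 27.9, FANCG beside VCP at 35.0 against 123 and MAD2L2, of translesion synthesis, at 21.8 against 54.6. Of 6 metallothioneins, 3 were lower and 1 higher with a median of -1.34 at percentile 0.24, MT1E beside MT2A being at 10.2 against 44.7. Of 45 oxidative phosphorylation genes, 13 were lower and 4 higher with a median of -0.71 at percentile 1.2, NDUFC1 being at 15.3 against 49.1. Housekeeping genes had a median of -0.94 over 12 genes at percentile 1.27, PPIA being at 12.1 against 25.6. Ribosomal protein genes had a median of 0.07 over 54 genes at percentile 99.9, with 4 higher and 4 lower, RPL37 being at 229 against 25.9. SNORD72, the next same-strand entry after RPL37, was at 839 against 570. The own or next entry moved NRF2 targets to percentile 12.9, metallothioneins to 8.92, housekeeping genes to 3.15 and the repair genes to 2.86.

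GLI1 beside INHBE stood at a log2 difference of 4.57 and GYPC (chromosome 2, 126656158 to 126696667), a glycophorin gene beside CNTNAP5, at 4.38. BBS2 beside NUDT21 was lower at 0.54 against 47.1, as was XRCC5 beside TMEM169 at 0.19 against 33.5. Of the 20 largest differences, 12 had a 0 on either side. In total 1344 entries were higher, 2226 lower and 10629 under 2-fold. The higher share of 37.6% was 55.0% after median-ratio scaling, 59.2% after rescaling to an equal sum and 51.8% after quantile scaling, and the median of all entries moved from -0.19 to 0.02 with median-ratio scaling.

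**Figure D5:**
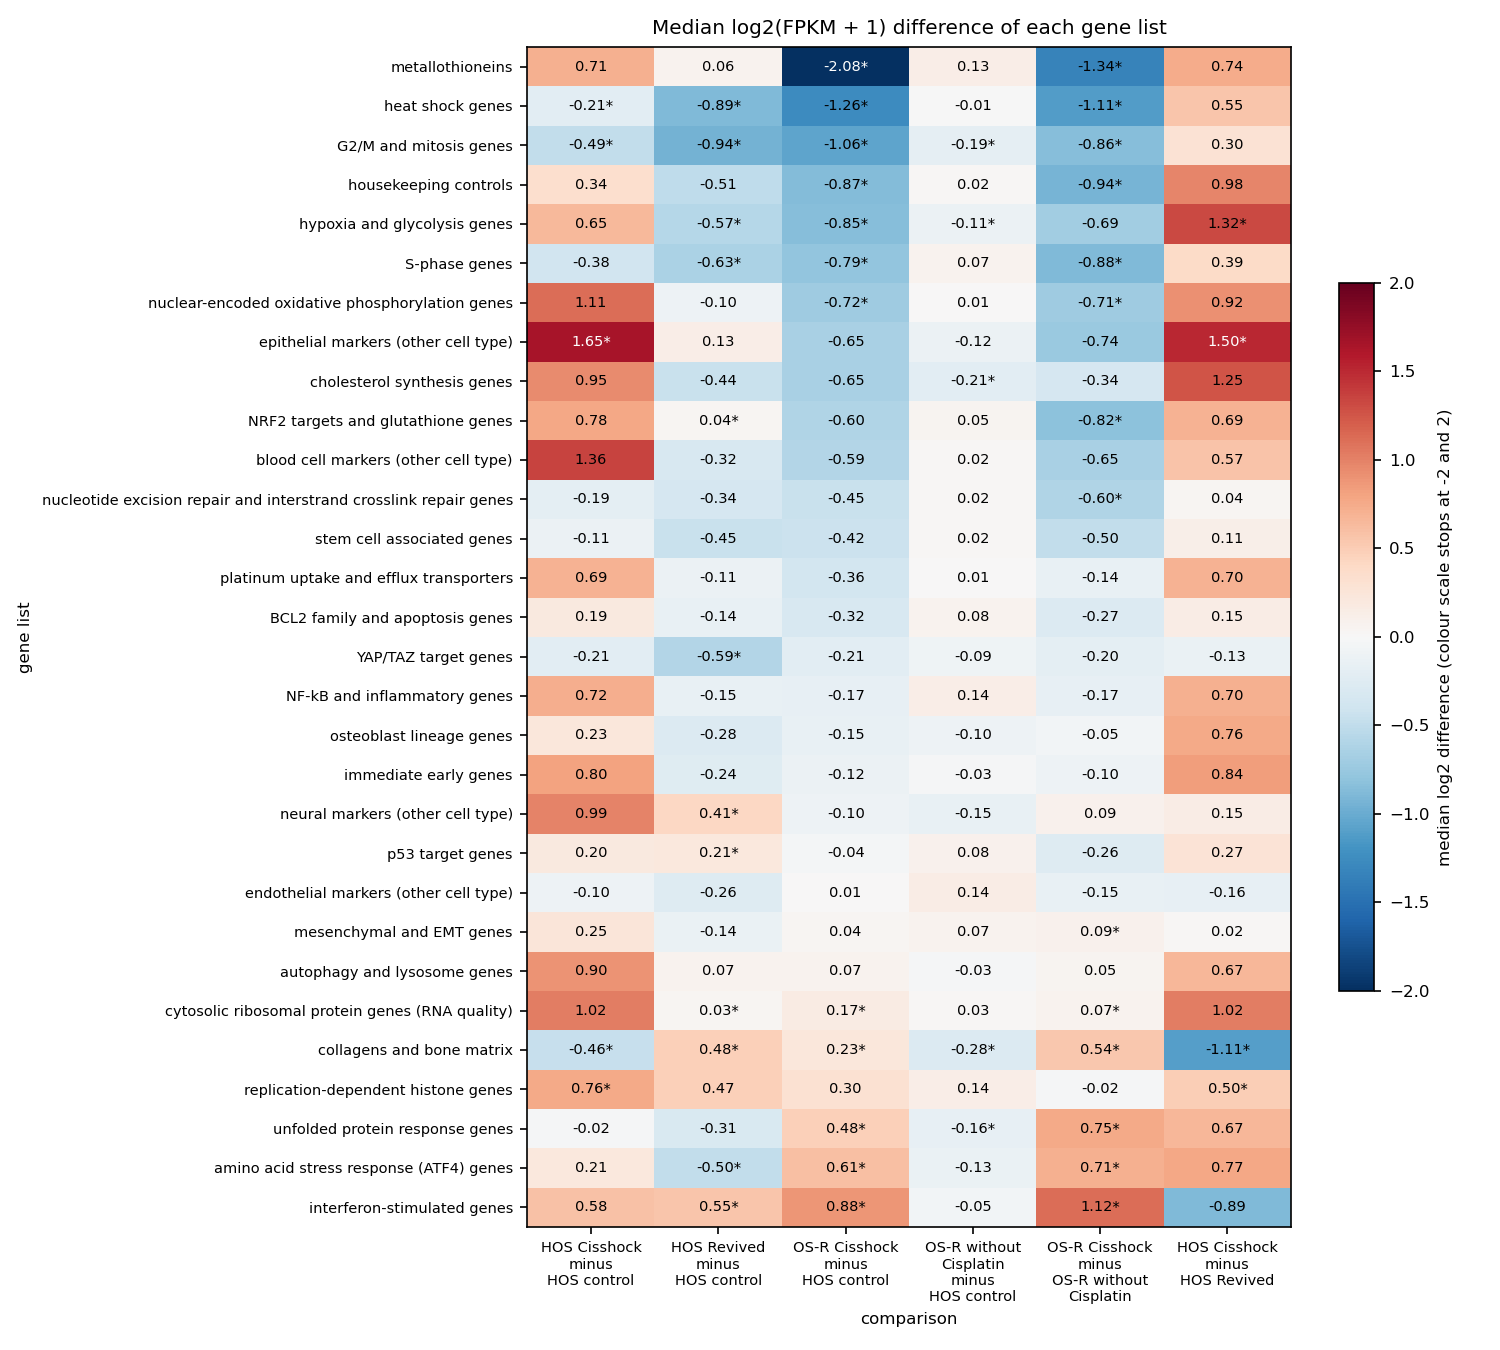
Median log2(FPKM + 1) difference of each gene list in the 6 comparisons, own entries, with colours capped at -2 and 2. An asterisk marks a median outside the middle 95% of random lists.

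What shocked and revived parental cells differed in is answered by HOS Cisshock against HOS Revived. Collagens were lower in HOS Cisshock, with COL11A1 at 1.07 FPKM against 17.3 and PLOD2 at 4.55 against 32.3. Glycolysis genes and epithelial markers were higher at the median as deposited but did not stand apart after GC centring, with ENO1, the enolase gene, at 3107 against 428 and PRSS8 at 50.9 against 9.10. FOSL1, an AP-1 subunit gene, was higher at 149 against 11.8, while ITGB1, a beta integrin gene, was lower at 15.2 against 132.

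Of 21 collagen and bone matrix genes, 11 were lower and 2 higher with a median of -1.11 at percentile 0, and DCN beside LUM was at 8.86 in HOS Revived and listed at 0 in HOS Cisshock. With the own or next entry their median was 0.05 at percentile 0.86, still below lists of equal level. Of 26 hypoxia and glycolysis genes, 16 were higher and 3 lower with a median log2 difference of 1.32 at percentile 97.8, including ALDOA, of aldol cleavage, at 264 against 42.3 and PFKP, a phosphofructokinase gene, at 620 against 110. Of 10 epithelial markers, 7 were higher and 2 lower with a median of 1.5 at percentile 98.1, EPCAM beside TTC7A being at 3016 against 337. Of 24 histone genes, 5 were higher and 5 lower with a median of 0.50 at percentile 99.2, H2BC26 being at 6.71 against 0.35 and H2AC21 at 2 against 7.63. Centring GC bins moved hypoxia and glycolysis genes to percentile 83.2, epithelial markers to 74.3 and histone genes to a median of -0.44 at percentile 56.5, and rescaling to an equal sum turned the histone median to -0.17. The own or next entry put hypoxia and glycolysis genes at percentile 96.2.

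SMURF2 beside DDX5 was lower at 0.71 against 1731, TET1 (chromosome 10, 68560337 to 68694487), a DNA demethylation gene beside HNRNPH3, at 0.60 against 36.9, and DMC1 beside DDX17 at 1.65 against 58.0. The SMURF2 entry was high in HOS Revived only. KIAA2013 beside NPPB was higher at 2384 against 57.7, ZC3H4 (chromosome 19, 47064187 to 47113776), beside TMEM160, at 155 against 3.77 and GMEB1 beside RAB42 at 149 against 0.80. Of the 20 largest differences, 10 had a 0 on either side. In total 4507 entries were higher, 3329 lower and 6319 under 2-fold. The higher share of 57.5% was 44.7% after median-ratio scaling, 16.8% after rescaling to an equal sum and 49.5% after quantile scaling, and the median of all entries moved from 0.29 to -0.05 and -0.78 with the first 2. The correlation with GC content was 0.513.

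Genes that handle platinum or respond to its damage were read in every comparison, as resistance can rest on them. Platinum uptake and efflux transporters had medians of 0.69 in HOS Cisshock, -0.11 in HOS Revived, -0.36 in OS-R Cisshock and 0.01 in OS-R without Cisplatin against HOS control, and did not stand apart from lists of equal level. Of 14 measured transporters in OS-R Cisshock, 1 was higher and 1 lower, SLC47A2, an organic cation exporter gene beside MFAP4, at 11.99 FPKM against 0.24 and ABCC5, an efflux pump gene, at 11.3 against 27.9. ATP7A, a copper exporter gene beside COX7B, stood at 155 against 276. In HOS Cisshock, LRRC8A, of the volume-regulated channel that takes up cisplatin, was at 65.2 against 15.4. Genes of nucleotide excision and crosslink repair had medians of -0.19, -0.34, -0.45 and 0.02 in the same order, and stood apart in OS-R Cisshock with the own or next entry at -0.58. Targets of p53 had medians of 0.20, 0.21, -0.04 and 0.08, with CDKN1A, a cell cycle inhibitor gene beside SRSF3, at 18.1 in OS-R Cisshock and 11.7 in OS-R without Cisplatin against 6.64 in HOS control. BCL2 family and apoptosis genes had medians of 0.19, -0.14, -0.32 and 0.08, with BAX, a pore-forming apoptosis gene, at 34.7 in OS-R Cisshock against 36.7 and MCL1, a survival gene, at 135 against 180.

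What the resistant line shared with and without the drug was read from entries 2-fold apart between both OS-R libraries and all 3 HOS libraries. There were 12 such entries higher and 5 lower in OS-R, the lowest total as deposited among the 10 ways to part the libraries 2 against 3, while after GC centring the OS-R pair had 17 and HOS control with HOS Revived had 16. AFAP1 (chromosome 4, 7758713 to 7939861), an actin filament regulator gene beside PSAPL1, was listed at 7.03 and 8 FPKM in OS-R Cisshock and OS-R without Cisplatin, and at 1.32, 0.25 and 2.58 in HOS control, HOS Cisshock and HOS Revived. LINC01537, a long noncoding RNA gene beside INPPL1, was at 6.75 and 6.98 against 1.69, 0.01 and 2.09. CHST14, a dermatan sulfotransferase gene beside BAHD1, was lower at 0.12 and 0.41 against 5.56, 9.98 and 2.72, and VCP beside SPATA31F3 at 8.69 and 2.81 against 25.4, 40.2 and 19.3. FANCG, for which VCP is the lower neighbour, was more abundant than the VCP entry in both OS-R libraries. Whether it carries values of VCP was not tested. UQCC3, a complex III assembly gene beside CSKMT, was listed at 0 in both OS-R libraries and at 21.6, 49.9 and 13.2 in the HOS libraries. Leaving out HOS Cisshock gave 32 higher and 15 lower. Parting OS-R Cisshock and HOS Revived from the other 3 gave 99 higher and 178 lower entries, with 121 and 108 after quantile scaling and 160 and 127 after GC centring. Across entries, the difference of OS-R Cisshock from OS-R without Cisplatin correlated at -0.334 with that of HOS Cisshock from HOS Revived and at -0.173 with that of HOS Cisshock from HOS control.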

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

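The readings from the own or next entry, the centring on GC content and every test of an explanation below were chosen after the results were seen.

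Collagen and bone matrix genes stood apart in opposite directions between cells with cisplatin shock and cells without cisplatin in the 2 lines. Their median was 0.54 in the resistant line, OS-R Cisshock minus OS-R without Cisplatin, and -1.11 in the parental line, HOS Cisshock minus HOS Revived. COL11A1, a fibrillar collagen gene, was listed at 27.4 FPKM against 4.06 in the resistant line and at 1.07 against 17.3 in the parental line. COL1A2, beside GNG11, was at 61.4 against 18.0 and at 21.2 against 122. In untreated HOS control COL11A1 was at 5.29 and COL1A2 at 27.2, so part of the parental difference lay in higher values of HOS Revived. Against HOS control the collagen median was higher in HOS Revived and lower in HOS Cisshock. The difference between the lines was not tested, since each group had 1 library. With the own or next entry the medians were 0.19 and 0.05, and after GC centring they were 0.72 and -1.31.

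HOS Cisshock lay further from each other library than those lay from one another, with at least 7325 entries 2-fold apart from each of them against at most 3570 among the other 4. A trend with GC content may be part of this, since the difference from HOS control correlated with GC content at 0.584, against at most 0.099 in size for differences among the other libraries. After centring on both GC contents, HOS Cisshock still had 5096 and 6278 entries 2-fold apart from HOS Revived and OS-R Cisshock, against at most 3324 among the others. From HOS control and OS-R without Cisplatin it had 3950 and 3763. Which transcript a displaced value belongs to is unknown, so this centring can leave part of a GC trend in place. Whether GC content is the whole of the distance is therefore left open. A difference in scale or distribution is unlikely to be the whole, as 5592 entries remained 2-fold apart from HOS control after quantile scaling, against at most 3383. A cisplatin response common to both lines would make the shock differences correlate above 0. After GC centring they correlated at -0.361 with HOS Revived as the parental baseline and at -0.18 with HOS control. As far as the labels hold, it is unlikely that such a response dominated these differences. The likeness of OS-R Cisshock to HOS Revived enters the first correlation with opposite signs and can lower it. Whether OS-R Cisshock was shocked is open, and HOS Cisshock has its own GC trend. A response shared by part of the entries is therefore left open. With HOS Revived and OS-R without Cisplatin exchanged, the correlation was -0.104, and from -0.167 to -0.069 under the other settings, which left the response open as well.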

How the results depend on the processing

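Counts, list medians and named genes were recomputed under the pseudocounts, filters, scalings and GC-bin centring, changing 1 setting at a time. The own or next entry was run for list medians, leaving out HOS Cisshock for the entries of both OS-R libraries and of single libraries, and centring on both GC contents for the pairs of libraries. Among counts and correlations 48 moved and 98 stayed, where a count moved by more than 1.5-fold and a correlation by more than 0.1 or by turning. Among list medians 20 moved, 15 reversed and 485 stayed, where a median moved if it shifted by more than the log2 of 1.5. A small list median could thus lose most of its size and still count as stayed. Among counts of entries set apart in a single library 40 moved and 58 stayed, and among named genes 394 moved and 830 stayed. Values are given by setting, with the main value first, and the cause was not tested. Comparisons are against HOS control unless another library is named. Leaving out repeated symbols was not run because no symbol was repeated, and leaving out small RNA symbols moved nothing. No paired analysis by replicate was possible because each group had 1 library and no replicate numbers were given, and the drug differences of the 2 lines were set against each other only by correlation. Depth was unknown, so zeros and small values could not be weighed by their reads.

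With a pseudocount of 0.1 in place of 1, entries higher and lower in HOS Revived went from 740 to 1309 and 1008 to 1596, and those in OS-R without Cisplatin from 447 to 798 and 424 to 779. Entries higher in OS-R Cisshock went from 1167 to 1799, and from 1344 to 2042 against OS-R without Cisplatin. Entries higher and lower in both OS-R libraries went from 12 to 49 and 5 to 54. Entries set apart in a single library went from 53 to 139 higher and 61 to 272 lower for HOS control, 295 to 556 and 352 to 716 for OS-R Cisshock, 57 to 121 and 45 to 253 for OS-R without Cisplatin, 66 to 154 and 63 to 235 for HOS Revived, and 1969 to 3170 lower for HOS Cisshock. The histone median in HOS Cisshock went from 0.76 to 1.47.

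With a pseudocount of 5, entries higher and lower went from 4266 to 2700 and 3477 to 1336 in HOS Cisshock, 740 to 122 and 1008 to 242 in HOS Revived, 1167 to 258 and 1956 to 862 in OS-R Cisshock, and 447 to 46 and 424 to 30 in OS-R without Cisplatin. They went from 1344 to 299 and 2226 to 1039 in OS-R Cisshock against OS-R without Cisplatin, and entries lower in HOS Cisshock against HOS Revived from 3329 to 1031. Entries higher and lower in both OS-R libraries went from 12 to 1 and 5 to 2. Single-library entries went from 53 to 9 and 61 to 4 for HOS control, 295 to 80 and 352 to 132 for OS-R Cisshock, 57 to 12 and 45 to 2 for OS-R without Cisplatin, 66 to 20 and 63 to 5 for HOS Revived, and 1969 to 581 lower for HOS Cisshock. The heat shock median in HOS Cisshock turned from -0.214 to 0.001, and that of interferon-stimulated genes in OS-R Cisshock against OS-R without Cisplatin went from 1.12 to 0.35.

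With at least 5 FPKM required, entries lower in HOS Cisshock went from 3477 to 2074, and from 3329 to 1760 against HOS Revived. Entries higher and lower went from 740 to 286 and 1008 to 584 in HOS Revived and from 447 to 110 and 424 to 82 in OS-R without Cisplatin. Entries higher in OS-R Cisshock went from 1167 to 526, and from 1344 to 636 against OS-R without Cisplatin. Entries higher in both OS-R libraries went from 12 to 4. Single-library entries went from 53 to 14 higher for HOS control, 295 to 174 higher for OS-R Cisshock, 57 to 21 higher and 45 to 24 lower for OS-R without Cisplatin, and 66 to 35 higher for HOS Revived. In HOS Cisshock the histone median went from 0.76 to 1.48 and the heat shock median turned from -0.21 to 0.68. In HOS Revived the ribosomal protein median turned from 0.032 to -0.001 and the neural median from 0.41 to -0.45. In OS-R Cisshock against OS-R without Cisplatin the metallothionein median went from -1.34 to -2.03 and the mesenchymal median turned from 0.09 to -0.07. With no filter, the metallothionein median in OS-R Cisshock went from -2.08 to -1.08.

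With median-ratio scaling, entries lower in OS-R Cisshock went from 1956 to 1283 and entries higher in HOS Cisshock alone from 2795 to 1792. With quantile scaling, entries higher in HOS Cisshock went from 4266 to 2627, from 4507 to 2955 against HOS Revived, and from 2795 to 956 for HOS Cisshock alone. The heat shock median in HOS Cisshock went from -0.21 to -0.88, the collagen median in OS-R Cisshock from 0.23 to 0.83, and the hypoxia and glycolysis median in HOS Cisshock against HOS Revived from 1.32 to 0.66.

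With each library rescaled to a sum of 1000000, entries higher and lower in HOS Cisshock went from 4266 to 859 and 3477 to 6192, and from 4507 to 1353 and 3329 to 6687 against HOS Revived. Entries higher went from 740 to 1500 in HOS Revived, 1167 to 2211 in OS-R Cisshock and 1344 to 2598 in OS-R Cisshock against OS-R without Cisplatin, and entries higher and lower in OS-R without Cisplatin from 447 to 709 and 424 to 763. Entries higher and lower in both OS-R libraries went from 12 to 36 and 5 to 16. Single-library entries went from 53 to 97 and 61 to 121 for HOS control, 295 to 706 higher for OS-R Cisshock, 57 to 90 and 45 to 97 for OS-R without Cisplatin, 2795 to 168 and 1969 to 4446 for HOS Cisshock, and 66 to 166 and 63 to 100 for HOS Revived. Medians in HOS Cisshock went from -0.49 to -1.40 for G2/M and mitosis, -0.21 to -1.23 for heat shock, -0.46 to -1.35 for collagens and 1.65 to 0.71 for epithelial genes, and turned from 0.76 to -0.14 for histones. Against HOS Revived they went from -1.11 to -2.17 for collagens, 1.32 to 0.24 for hypoxia and glycolysis and 1.5 to 0.51 for epithelial genes, and turned from 0.50 to -0.17 for histones. The metallothionein median in OS-R Cisshock went from -2.08 to -0.91.

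The next 3 settings were added after the data were seen. With GC bins centred, entries higher in HOS Cisshock went from 4266 to 2026, from 4507 to 2639 against HOS Revived, and from 2795 to 1134 for HOS Cisshock alone. In HOS Cisshock the G2/M and mitosis median turned from -0.49 to 0.044 and the epithelial median went from 1.65 to 0.64. Against HOS Revived the histone median turned from 0.50 to -0.44, hypoxia and glycolysis went from 1.32 to 0.55, and epithelial genes from 1.5 to 0.41. With the own or next entry, the heat shock median in HOS Cisshock turned from -0.21 to 0.60, and collagens in HOS Cisshock against HOS Revived from -1.11 to 0.045. In HOS Revived p53 targets turned from 0.21 to -0.16, NRF2 targets from 0.045 to -0.029 and neural markers from 0.41 to -0.23. The metallothionein median in OS-R Cisshock went from -2.08 to -0.97, and mesenchymal genes in OS-R Cisshock against OS-R without Cisplatin turned from 0.09 to -0.12. With HOS Cisshock left out, entries higher and lower in both OS-R libraries went from 12 to 32 and 5 to 15. Single-library entries went from 53 to 82 and 61 to 98 for HOS control, 57 to 100 and 45 to 86 for OS-R without Cisplatin, and 63 to 97 lower for HOS Revived.

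Some lists stood apart with an added setting but not by their own entries as deposited. The number of lists that stood apart went with the own or next entry from 5 to 7 in HOS Cisshock, 12 to 16 in OS-R Cisshock, 5 to 9 in OS-R without Cisplatin, 14 to 12 in OS-R Cisshock against OS-R without Cisplatin and 4 to 6 in HOS Cisshock against HOS Revived, and was 12 with either in HOS Revived. Gained with it in HOS Cisshock were S-phase genes at percentile 0.72, YAP and TAZ targets at 1.64, ribosomal protein genes at 0.26 and neural markers at 98.6. In HOS Revived histones were gained at 99.7, autophagy genes at 99.9 and oxidative phosphorylation genes at 97.7. In OS-R Cisshock repair genes were gained at 1.26, cholesterol synthesis at 0.70, mesenchymal genes at 99.4, osteoblast genes at 99.8, autophagy genes at 100 and endothelial markers at 99.1. In OS-R without Cisplatin S-phase genes were gained at 100, metallothioneins at 99.8, NF-kB genes at 99.1, immediate early genes at 100 and amino acid stress genes at 0. Against OS-R without Cisplatin, OS-R Cisshock gained osteoblast genes at 99.8, autophagy genes at 100 and hypoxia and glycolysis genes at 1.46. Against HOS Revived, HOS Cisshock gained mesenchymal genes at 0.33, cholesterol synthesis at 97.6 and ribosomal protein genes at 0.03. GC centring gained mesenchymal genes at percentile 1 and oxidative phosphorylation genes at 99.2 in HOS Cisshock, and histones at 98.6 in HOS Revived. In HOS Cisshock against HOS Revived it gained p53 targets at 1.15, S-phase genes at 99.0, G2/M and mitosis genes at 100, amino acid stress genes at 97.7 and oxidative phosphorylation genes at 97.55.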

Other observations

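Every test of an explanation in this part was chosen after the result was seen.

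Osteoblast, stem cell, immediate early, NF-kB and autophagy genes did not stand apart in any of the 6 comparisons by their own entries. With the own or next entry, osteoblast and autophagy genes stood apart in OS-R Cisshock against HOS control, with medians of 0.27 and 0.23, and against OS-R without Cisplatin, with 0.30 and 0.25. So did autophagy genes in HOS Revived at 0.11, and NF-kB and immediate early genes in OS-R without Cisplatin at 0.14 and 0.22. Osteoblast genes, which mark the bone-forming lineage, had medians of 0.23 in HOS Cisshock, -0.28 in HOS Revived, -0.15 in OS-R Cisshock and -0.10 in OS-R without Cisplatin against HOS control. ID1, a BMP-induced inhibitor of differentiation with HM13 as lower neighbour, was at 12.8 FPKM in OS-R Cisshock against 82.3, and RUNX2, the bone lineage regulator, at 6.97 against 4.56. Stem cell genes had medians of -0.11, -0.45, -0.42 and 0.02 in the same order, with NES, an intermediate filament gene, at 8.61 in OS-R Cisshock and 10.4 in HOS Revived against 25.7, and CD44, a hyaluronan receptor gene, at 39.3 and 31.2 against 46.7. Immediate early genes had medians of 0.80, -0.24, -0.12 and -0.03, with FOSL1, of the AP-1 factor, at 149 in HOS Cisshock, 11.8 in HOS Revived, 10.4 in OS-R Cisshock and 75.2 in OS-R without Cisplatin against 47.9. DUSP6, a phosphatase that dampens ERK, was at 8.85 in OS-R Cisshock against 1.80.

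NF-kB and inflammatory genes had medians of 0.72, -0.15, -0.17 and 0.14 in that order, with the chemokine gene CXCL1 at 7.96 in OS-R Cisshock and 40.1 in HOS Cisshock against 24.6. Autophagy and lysosome genes had medians of 0.90, 0.07, 0.07 and -0.03, with LAMP2, a lysosomal membrane gene, at 12.1 in OS-R Cisshock against 3.42 and BECN1, which starts autophagosomes, at 20.6 against 56.2. Blood cell markers had medians of 1.36, -0.32, -0.59 and 0.02, and PTPRC, a leukocyte gene beside NEK7, stood at 1.29 in HOS Cisshock against 32.1. Endothelial markers had medians of -0.10, -0.26, 0.01 and 0.14, with CLDN5 at 120 in HOS Cisshock and 20.8 in OS-R Cisshock against 44.5.

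Part of the members of abundant families had their values away from their own entries, with the next entry higher in 32 of 59 ribosomal protein genes and 26 of 47 oxidative phosphorylation genes in HOS control. In the library where the contrast was lowest, entries next to ribosomal protein genes at higher coordinate exceeded those at lower coordinate by 7.12 on the log2(FPKM + 1) scale at the median. The displacement was not limited to these families. The lowest contrast over the libraries was 2.501 for housekeeping genes, 1.717 for unfolded protein response genes and 0.872 for G2/M and mitosis genes. In HOS control the next entry was higher in 6 of 11, 10 of 16 and 27 of 48 of them in that order. These contrasts restate the observation in the same libraries. Values listed under the identifier of the next gene therefore remain a candidate explanation that was not tested on other data. Reads shared with pseudogenes elsewhere in the genome would not favour the entry at higher coordinate over that at lower coordinate. Oxidative phosphorylation genes gave a contrast of at least 3.21, so shared reads are unlikely to explain the side of the high values. Pseudogenes were not counted for either family, and whether shared reads lower the own entries was not tested. No biological explanation was tested, and which entries are displaced was not settled.

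OS-R Cisshock was closest to HOS Revived, at a correlation of 0.905, and OS-R without Cisplatin to HOS control, at 0.949, while HOS Revived was itself slightly closer to HOS control at 0.918 and to OS-R without Cisplatin at 0.917. A trend with GC content or level is unlikely to explain this. After quantile scaling, which bears on level, 229 entries parted OS-R Cisshock and HOS Revived from the other 3 libraries, against at most 76 for any other way to part them 2 against 3. After GC centring 287 entries did so, against at most 47. Exchanged labels of OS-R without Cisplatin and HOS Revived cannot be told apart from a biological likeness, as the exchange would give 277 entries between the lines, against at most 90 for any other parting. A lower share of dividing cells stays open, as S-phase and G2/M genes or their next entries made up 5.1% of those 277, against 1.3% of all entries, all 14 of them among the 178 lower, while these lists are too short to show whether it could be the whole.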
